A study of Homo sapiens with 2 samples.

How the data were processed

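RNA of 2 samples of the breast cancer line MDA-MB-231 was sequenced, 1 wild type and 1 with TMEM25 knocked out. The labels give the genotype under the name TAMER, taken here as TMEM25 because the series design names TMEM25 as the gene knocked out. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, RNA was extracted with TRIzol and the libraries were made following protocols of the sequencing provider BGI. The submitters' processing notes name CASAVA 1.4, HISAT2 2.0.4 and genome build GRCh38.p12. The counting tool, the gene annotation and whether strand was used are not given in the sources used here.

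The authors deposited 1 table, which gives per gene an Entrez number, a symbol and values of both libraries. Per the file headers, each library has an expression value, used here as a signal scaled for gene length and library depth, whose unit (FPKM or TPM) is not named. Each library also has a read count, which the authors deposited as an expected count, not whole in 43.7% of genes for the knockout and 40.7% for the wild type. The deposited ratio is the knockout value over the wild-type value, which holds in 2046 of 2046 genes (tolerance 1e-06 of the ratio). Where the wild-type count is 0 the deposited wild-type value is 0.1, in 100 of 100 such genes. The authors also deposited log2 ratios of each library over the mean of both. Their headers are crossed, as the column headed for the wild type holds log2 of the knockout over the mean in 2046 of 2046 genes (tolerance 1e-06), and these columns were not used. The direction of every difference reported here therefore rests on the headers of the expression, count and ratio columns, which point the same way in 2046 of 2046 genes. All columns used were matched to a sample by genotype, and the number not matched was 0.

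All 2046 genes have a deposited ratio of at least 2 and a knockout value of at least 1, so the table holds genes within those limits only. Shares of a gene list are therefore counts of members among these genes, no enrichment was tested because the genes that could have been listed are not known, and no library total could be formed. Of the Entrez numbers, 2034 matched the RefSeq gene table used for names, 2012 of them protein coding, 15 lncRNA and 7 pseudogenes, and 12 had no match. In 2 genes the symbol had been turned into a date, which the Entrez numbers give as SEPTIN1 and MARCHF10, and 4 symbols were bare numbers. Coordinates are from GENCODE 29 on GRCh38, joined by Entrez number for 2013 genes.

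The log2 ratio of each gene was log2((knockout + 1) / (wild type + 1)) on the deposited expression values, which understates the ratio of low genes. Genes were kept at a value of at least 1 in either library, which kept all 2046, and were called 2-fold higher by size alone. The planned scaling for counts was set aside because only part of each library was held. The read-count fold was the ratio of the counts divided by 1.155, the median ratio of reads per unit of expression between the libraries over 1133 genes with at least 100 wild-type reads, of which 86.4% lay within 5% of it. Its 95% interval was the exact conditional binomial interval on rounded counts. Intervals and the floor of 3 reads that stands for a count of 0 cover counting error only, and reads without molecular identifiers are not independent molecules. The expression values and the read-count fold differ for some genes, for a reason not given in the sources used here.

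Gene lists were written before the data were examined: 23 pathway lists with 458 genes, of which 108 (23.6%) were among the listed genes, 5 quality lists and 7 lists of cell type markers. The median log2 ratio of a list with at least 5 members present was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, and a list stood apart below the 2.5th or above the 97.5th percentile. Of the 11 lists placed, 2 stood apart. By construction about 5% of random lists lie outside these limits. Some of the lists share members, so their placements are not independent. Genes named in the text are TMEM25, EGFR and STAT3, the 10 highest and 10 lowest log2 ratios among genes with a value of at least 5, all members of the STAT3 target, JAK-STAT and EGFR lists that were at least 2-fold different, up to 3 members of other lists that stood apart and up to 2 of lists that did not, and markers of cell types. Members below 2-fold and further members named beside these were chosen after their values were seen.

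On simulated counts, the 95% interval held the true fold for 93.5%, 96.0% and 96.5% of 200 genes at 2-, 4- and 10-fold. These were drawn from the 1821 genes of this comparison with at least 5 wild-type reads. Intervals for genes with fewer wild-type reads or at higher folds were not checked in this way. Of 100 random lists of 12 of the 2046 genes, 2% stood apart, and 100% did after 1 log2 unit was added. Tests along the chromosomes used 17202 protein-coding genes after leaving out silent or tandem gene families, 1885 of them listed. In 100 simulations any of those genes could be listed, and both measures were set against permutations that moved blocks of genes. Listing exceeded these at 5 to 10 Mb in 4% without a planted region and in 44% with 10 planted regions. Likeness of ratios did so in 4% and 32% of 100 simulations over the 1885 genes. Alternatives were pseudocounts of 0.1 and 5, 3 scalings, 2 filters on low values, rules of 1.5- and 4-fold, unmatched random lists, the mean of members and lists without shared members, and 3 counts added after the data were seen. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.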

Results

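The series compared messenger RNA of wild-type MDA-MB-231 cells, a human triple-negative breast cancer line, with that of the same line after knockout of TMEM25, which encodes a transmembrane protein. Its title places the comparison in the question of how monomeric EGFR, the epidermal growth factor receptor, activates the transcription factor STAT3. Each genotype had 1 library, so no difference reported here has a replicate check and no test was made. The table analysed here held 2046 genes, and in all 2046 the knockout value was at least 2 times the wild-type value and at least 1. It therefore describes genes that were higher in the knockout library, and genes that were lower or alike were not analysed here. TMEM25, EGFR and STAT3 were not among these genes and were not analysed here, so the loss of TMEM25 RNA could not be checked. Which library is called the knockout rests on the headers of the expression, count and ratio columns, because the headers of the log2 columns run the other way. The reads assigned to these genes summed to 4138956 in the knockout library and 1046999 in the wild-type library. These sums cover part of each library and are not its depth. The median gene had 677.8 reads in the knockout library and 142 in the wild-type library, while 322 genes had under 10 wild-type reads and 100 had 0.

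The 2 libraries were far apart for many genes. Per the authors' deposited table, the median ratio of knockout to wild type was 3.33, with an interquartile range of 2.42 to 7.29. The ratio was at least 4 for 842 genes, at least 10 for 412 and at least 100 for 75. On the log2(value + 1) scale, 1650 of the 2046 genes were at least 2-fold higher in the knockout library, with a median log2 ratio of 1.33 (SD 0.91 across genes, 1st and 99th percentiles 0.58 and 5.22). The remaining 396 fell short of 2-fold on this scale because the pseudocount of 1 lowers every ratio, most of all at low values. With a pseudocount of 5, 844 genes reached 2-fold, and 232 to 279 did under the 3 scalings, while 436 genes reached 4-fold. These falls follow from the rules themselves, as do those of list members given below. The scalings lower every ratio in a table selected for ratios of at least 2. Across these genes the log2 values of the libraries correlated with a Pearson r of 0.90 and a Spearman rho of 0.86, both computed on genes, which are not independent replicates and were selected for their ratio. The 95% counting interval of the read-count fold lay above 2 for 1566 genes, included 2 for 468 and lay below 2 for 12.

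**Figure D1:**
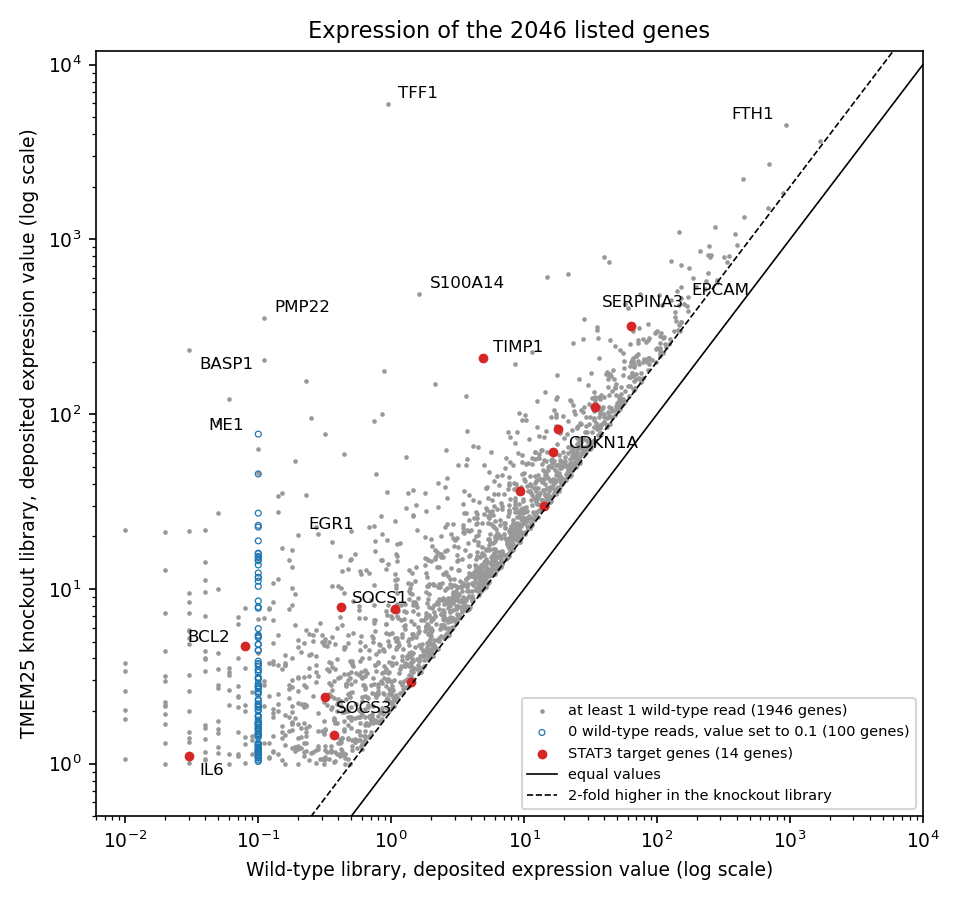
Deposited expression values of the 2046 listed genes in the wild-type library (horizontal axis, log scale, unit not named) and the TMEM25 knockout library (vertical axis, log scale), 1 point per gene and 1 library per genotype, with STAT3 target genes in red and the 100 genes without a wild-type read as open blue circles. All points lie on or above the dashed line of 2-fold, as the listed genes all have a ratio of at least 2, and TFF1 has the highest knockout value at 5920 against 0.94.

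Among genes with a value of at least 5, the highest log2 ratio belonged to TFF1, which encodes the secreted trefoil factor 1, an estrogen-responsive product of luminal breast cells. Its value was 5920 in the knockout library and 0.94 in the wild-type library, a log2 ratio of 11.58, from 50724 and 7 reads. The read-count fold was 6272, with a 95% counting interval of 3044 to 15601. TFF1 lies on the minus strand of chromosome 21 from 42362282 to 42366594 in GRCh38. TFF3, its neighbour from 42311667 to 42315651, had values of 127.85 and 3.68 and a read-count fold of 34.7 (26.9 to 45.5). The next highest were PMP22, a myelin membrane protein also made outside nerve (353.94 against 0.11, log2 ratio 8.32), and BASP1, a membrane-bound signalling protein (233.32 against 0.03, log2 ratio 7.83). PMP22 had 3 wild-type reads, for a fold of 3393 with a counting interval of 1161 to 16454. BASP1 had 1 wild-type read, so its fold of 6850 had a counting interval of 1229 to 270597. SULF2, an extracellular sulfatase, followed at 204.81 against 0.11, and S100A14, a calcium-binding protein of epithelia, at 484.5 against 1.63, with log2 ratios of 7.53 for both. The other 5 of the 10 highest were CSTA, a cysteine protease inhibitor of keratinocytes, LXN, a carboxypeptidase inhibitor, TPM4, a tropomyosin, SLC7A2, a cationic amino acid transporter, and AKR1C1, an aldo-keto reductase, with log2 ratios of 6.98, 6.87, 6.55, 6.43 and 6.26. AKR1C1 shares much of its sequence with AKR1C2, so its value depends on how shared reads were divided. The 10 lowest log2 ratios under the same rule ran from 0.80 to 0.84, at ratios of at most 2.11 in the authors' deposited table. They included TMEM45A (5.45 against 2.71), CTC1, a telomere maintenance protein (5.48 against 2.66), and NFE2L3 (5.28 against 2.54). These lie at the limit of the table and are not the genes lowest in the knockout library.

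Genes described as STAT3 targets were the group closest to the stated question. Of the 31 in the list, 14 were among the genes higher in the knockout library, and 12 of these reached 2-fold on the log2(value + 1) scale, while the other members were not analysed here. That count was 7 with a mean of at least 5 in the libraries and 3 under each of the 3 scalings, which bring the median log2 ratio of the listed genes to at most 0.02. Under the 4-fold rule 6 members passed. The luminal markers TFF1 (5920 against 0.94) and TFF3 (127.85 against 3.68) were higher in the same library, beside this group and those that follow. TIMP1, an inhibitor of matrix metalloproteinases on chromosome X (47582313 to 47586789, GRCh38), had the highest log2(value + 1) ratio of the list, 5.16, at 208.87 against 4.89, and a read-count fold of 42.8 (33.8 to 55.0). SERPINA3, an acute-phase protease inhibitor, was at 321.17 against 63.88, with a fold of 5.03 (4.77 to 5.31). SOCS1 and SOCS3, which feed back on cytokine receptor signalling, were at 7.84 against 0.42 and 2.42 against 0.32, with folds of 18.8 (9.35 to 44.3) and 7.60 (4.36 to 14.3). BCL2, an inhibitor of apoptosis, rested on 461 and 3 reads, for a fold of 133 (45.2 to 647), while its deposited values of 4.71 and 0.08 give a smaller ratio. CDKN1A, a cell cycle inhibitor, CEBPB and CEBPD, transcription factors of the acute-phase response, BCL3, a co-regulator of NF-kB, and FOS had folds of 4.55, 3.65, 3.89, 3.24 and 7.14. IL6 stayed near the lower limit at 1.10 against 0.03, and OSMR, the oncostatin M receptor, was at 29.79 against 14.1. The median log2 ratio of the 14 members was 1.83. It lay at the 99.1st percentile of 10000 random lists of the same size matched on mean expression within these genes, which describes the size of the ratio in these libraries only. The call did not hold up well, as 7 of 8 alternatives that gave another placement put the list inside the middle 95% of random lists, at percentiles of 86.0 to 96.0. The lowest came from the 5 members shared with no other list, and unmatched random lists kept the call at 97.6. The placements at 95.7 and 96.0 came from scalings, which take the one-sided selection of the table as a shift between the libraries. Pseudocounts of 0.1 and 5, which involve no scaling, gave 92.8 and 95.9.

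Of the 28 genes of the IL-6 family and the JAK-STAT pathway, 9 were among the genes higher in the knockout library and all 9 reached 2-fold. That count was 2 with a pseudocount of 5, 4 with a mean of at least 5 in the libraries and 1 under each of the 3 scalings. Under the 4-fold rule 2 passed, and all of these counts are lower by construction. The group held negative regulators, namely SOCS1, SOCS2, SOCS3 and the phosphatases PTPN1, PTPN2 and PTPN6, and the receptors LIFR and OSMR, beside IL6. PTPN2 was at 31.85 against 15.07 with a read-count fold of 1.88 (1.68 to 2.10). PTPN6 was at 25.31 against 4.43 with a fold of 5.74 (4.84 to 6.84), and LIFR, the leukemia inhibitory factor receptor, at 6.33 against 0.91 with a fold of 7.21 (6.07 to 8.63). SOCS2 had 97 reads in the knockout library and 0 in the wild-type library, a fold of 28.0 when 3 reads stand for the 0. The counting interval puts its lower limit at 22.3, and the ratio in the authors' deposited table, which takes a value of 0.1 for the 0, was 22.9. The list's median log2 ratio of 1.37 lay at the 65.2nd percentile of matched random lists. Of the 23 genes of the EGFR family, its ligands and its regulators, 3 were among these genes. The adaptor GRB2 was at 110.73 against 49.41 with a fold of 2.25 (2.15 to 2.35), and the ligands EGF and HBEGF were at 4.16 against 2.06 and 1.72 against 0.58, below 2-fold on the log2(value + 1) scale. Immediate early and ERK feedback genes gave 12 of 27, of which 10 reached 2-fold. With a pseudocount of 5 that number was 5, and it was 2 under each of the 3 scalings, while 3 reached 4-fold, all lower by construction. EGR1, a growth factor-induced transcription factor, was at 20.41 against 0.20 with a fold of 103 (55.8 to 215), and DUSP4, a phosphatase acting on ERK, at 43.09 against 2.61 with a fold of 16.5 (14.5 to 18.8). That list's median of 1.19 lay at the 25.7th percentile.

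**Figure D2:**
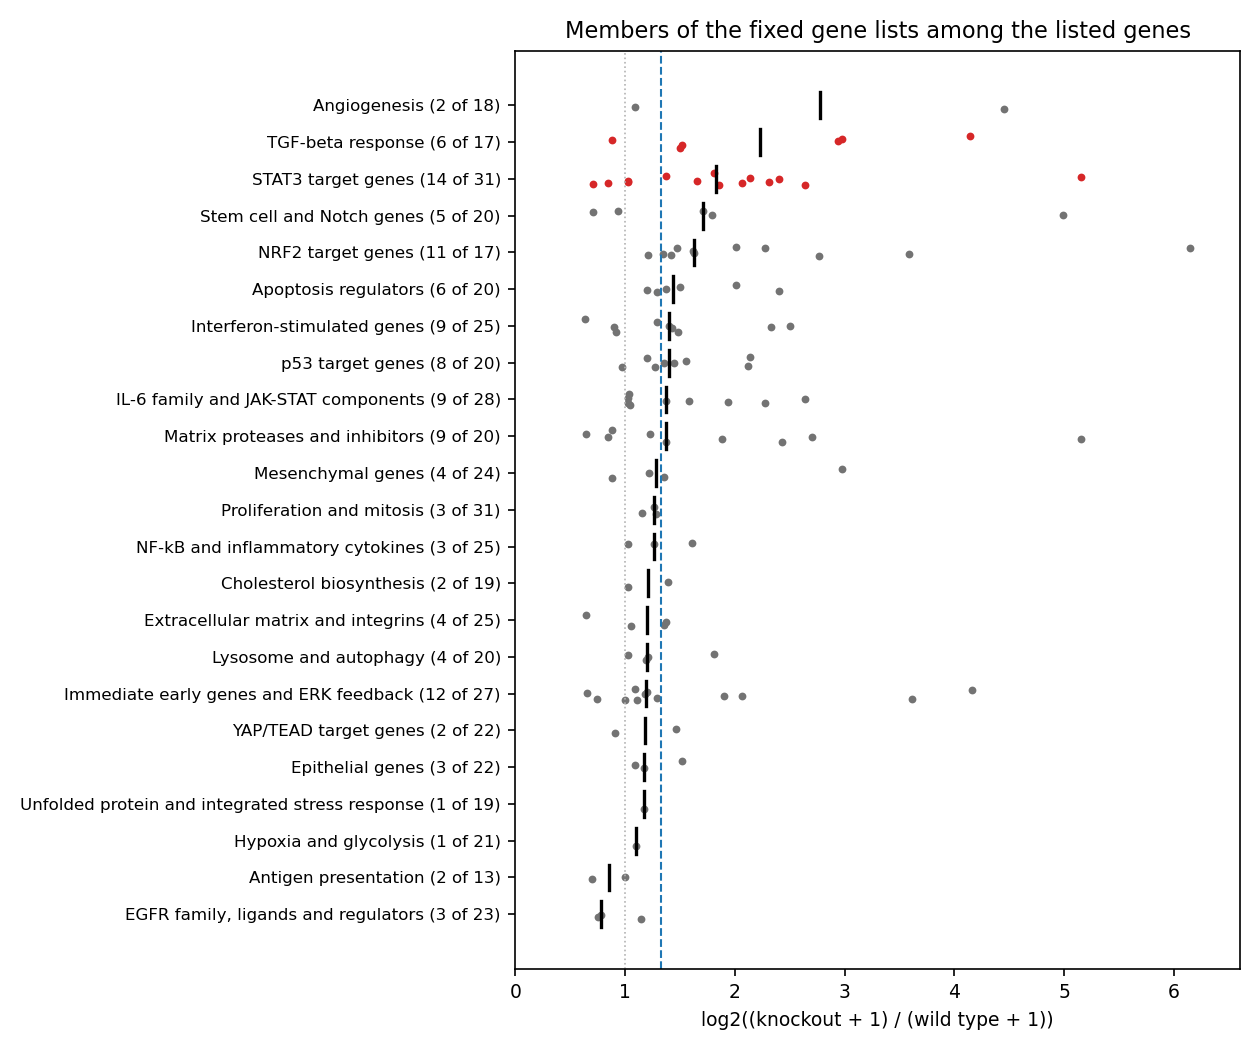
Log2 ratio of knockout over wild-type value (pseudocount 1, 1 library per genotype) for each member of the fixed pathway lists that was among the listed genes, 1 point per gene, with the number of members and the size of the list in brackets, the list's median as a black bar, the median of all listed genes (1.33) as a dashed line and 2-fold as a dotted line. The 2 lists in red, STAT3 target genes at a median of 1.83 and TGF-beta response at 2.23, lay above the middle 95% of matched random lists.

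The TGF-beta response list also lay high, with 6 of 17 members among these genes, 5 of them at least 2-fold higher, a median log2 ratio of 2.23 and a percentile of 98.2. TGFB1, the ligand, was at 62.13 against 2.57 with a fold of 23.5 (19.2 to 29.03), TGFBI, a matrix protein it induces, at 10.18 against 0.42 with a fold of 24.1 (15.3 to 40.4), and the receptor TGFBR2 at 6.99 against 0.04, from 584 and 4.06 reads. The percentile was 95.6 with a pseudocount of 5 and 95.4 for the mean of the members, inside the middle 95%. NRF2 target genes, which serve antioxidant defence and NADPH supply, had the largest share of members present, 11 of 17, all at least 2-fold higher. Under the 4-fold rule 5 passed, and 3 were at least 2-fold higher under each of the 3 scalings, both lower by construction. ME1, the cytosolic malic enzyme, had 3732 reads against 0, a fold of 1077 when 3 reads stand for the 0. The lower limit of its counting interval was 875, and its ratio in the authors' deposited table was 769. The ferritin chains FTH1 and FTL were at 4487 against 928.06 and 852.84 against 210.97. The NRF2 list's median of 1.63 lay at the 90.4th percentile. The mean of the members lay at 98.6. Equal totals without the 50 most abundant genes gave 97.9 and median-of-ratios size factors 97.8. Both are scalings, which take the one-sided selection of the table as a shift between the libraries. Other placements lay inside the middle 95%. They were 97.455 and 95.9 with pseudocounts of 0.1 and 5, and 95.2 with a mean of at least 5 in the libraries. Unmatched random lists gave 88.3, and leaving out shared members gave 90.4.

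The other pathway lists with at least 5 members present lay inside the middle 95% of random lists. Matrix proteases and inhibitors gave 9 of 20 (median 1.37, percentile 72.0), with TIMP3 at 5.72 against 0.03 from 3 wild-type reads. Interferon-stimulated genes gave 9 of 25 (percentile 69.2), with ISG15 at 20.74 against 2.83 and OAS1 at 15.76 against 2.34. The p53 target genes gave 8 of 20 (percentile 56.5), with SESN1, a stress-induced metabolic regulator, at 13.36 against 2.30. Stem cell and Notch genes gave 5 of 20 (median 1.71, percentile 90.8), with the drug efflux transporter ABCG2 at 35.57 against 0.15 and SOX2 at 32.01 against 8.54. Apoptosis regulators gave 6 of 20 (median 1.43, percentile 52.8), including the pro-apoptotic BCL2L11 at 18.22 against 3.76. Lists with fewer members present were given values only. Mesenchymal genes gave 4 of 24, with ITGA5 at 8.66 against 2.79 beside TGFBI, and epithelial genes 3 of 22, with EPCAM at 419.58 against 145.74 and MAL2 at 239.36 against 105.63. NF-kB and inflammatory cytokine genes gave 3 of 25, with NFKBIA at 264.72 against 86.08 and CXCL8 at 2.36 against 0.40. Proliferation and mitosis gave 3 of 31, with MCM7 at 131.06 against 53.18 and TYMS at 79.22 against 32.39. Extracellular matrix and integrins gave 4 of 25, lysosome and autophagy 4 of 20, with SQSTM1 at 452.73 against 128.29, and angiogenesis 2 of 18, with the co-receptor NRP1 at 21.83 against 0.04 from 3 wild-type reads. YAP/TEAD targets gave 2 of 22, cholesterol biosynthesis 2 of 19, antigen presentation 2 of 13, hypoxia and glycolysis 1 of 21 and the unfolded protein response 1 of 19.

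Measures of RNA quality and cell identity stood beside these groups. Of the quality lists, none of the 13 mitochondrially encoded mRNAs, 2 of 41 ribosomal protein genes, 2 of 13 histone genes and 2 of 25 housekeeping genes were among the genes higher in the knockout library, including RPL10 at 641.03 against 243.78 and HPRT1 at 33.17 against 12.44. Heat shock genes gave 5 of 13, with HSPH1 at 47.65 against 13.82 and a median at the 32.1st percentile. Markers of luminal breast cells gave 2 of 12, TFF1 and TFF3. Basal and squamous keratinocyte markers gave 1 of 10, SFN at 159.55 against 69.09, endothelial markers 1 of 8, EMCN at 4.73 against 0.33, and neural markers 2 of 8, TUBB3 at 49.0 against 7.17 and SOX2. Fibroblast, leukocyte and hepatocyte markers gave 0 of 10, 0 of 12 and 0 of 8. After leaving out silent or tandem gene families, the share of protein-coding genes that were listed differed by chromosome, from 4.5% on chromosome 11 to 19.2% on chromosome X, and how many of the unlisted genes are silent in these cells is not known.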

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

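The ratio as deposited, the ratio of read counts and the limit on the counting interval were chosen as alternatives after seeing the data, and the others before the data were examined. The count of 1650 genes at least 2-fold higher in the knockout library was 2011 with a pseudocount of 0.1 and 844 with a pseudocount of 5. It was 2046 from the ratio as deposited, 1986 from read counts and 1566 when the lower limit of the counting interval had to exceed 2. Under the 4-fold rule 436 genes passed. Of 12 STAT3 target genes at least 2-fold higher, 7 were left with a mean of at least 5 in the libraries and 6 under the 4-fold rule, and 8 with a pseudocount of 5, each by construction of the stricter rule. Scaling alternatives take the one-sided selection of the table as if it were a shift between the libraries, since they bring the median log2 ratio of the listed genes from 1.33 to at most 0.02. Under centring on the median, equal totals without the 50 most abundant genes and median-of-ratios size factors, 279, 242 and 232 genes and in each case 3 STAT3 target genes were at least 2-fold higher, and 0 genes were at least 2-fold lower. The number of gene lists standing apart was 2, against 1 with a pseudocount of 0.1, 0 with a pseudocount of 5, 0 with a mean of at least 5 in the libraries, 1 for the mean of the members and 0 for lists without shared members. The TGF-beta list kept 4 members under the last of these and under the mean of at least 5, and was not placed there. With equal totals without the 50 most abundant genes and with median-of-ratios size factors the number was again 2, but STAT3 target genes were no longer apart (95.7 and 96.0) and NRF2 target genes were (97.9 and 97.8). For the mean of the members the list apart was NRF2 target genes (98.6). The cause was not tested. Of 80 list placements under alternatives, 68 kept their side of the limits, but the STAT3 target genes kept theirs in 1 of 8, at 97.6, and lost it in the other 7, at 86.0 to 96.0. Of 160 log2 ratios of named genes under other pseudocounts, 73 were called moved, judged by the size of the shift against the width of the counting interval. A value not called moved need not lie inside that interval. All 160 kept their sign because every listed gene was higher in the knockout library. The TMEM25 ratio gave no value under any setting, and a count of genes at least 2-fold lower says nothing of the cells, since listed genes were all higher. No paired analysis was possible because each genotype had 1 library. Depth limits the 322 genes with under 10 wild-type reads, whose folds are known only within wide intervals.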

Other observations

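Except for the likeness of ratios between genes 5 to 10 Mb apart, the tests in this part were chosen only after the pattern was seen. Genes without a wild-type read formed a group of 100, and the most deeply covered of them were chosen here after their values were seen. LPIN2, a phosphatidate phosphatase, had 1824 reads in the knockout library, CTNND2, a catenin of neural tissue, 1772, HENMT1, a methyltransferase of small RNAs, 1405, WIPF1, an actin regulator, 1331, and KCNJ3, a potassium channel, about 1253. Taking 3 reads for the 0, their folds were 526, 511, 405, 384 and 362, while the lower limits of their counting intervals were 428, 415, 329, 312 and 294. Their ratios in the authors' deposited table, which takes a value of 0.1 for the 0, were 159, 231, 455, 153 and 145. GSTT1, a glutathione transferase whose gene is deleted in many human genomes, had 395.74 reads against 0. Its fold was 114 when 3 reads stand for the 0, with a lower limit of 92.5 from the counting interval and a ratio of 226 in the authors' deposited table.

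Listed genes were not spread evenly over the genome. In windows of 10 Mb with at least 20 protein-coding genes, the highest shares were 8 of 20 on chromosome 5 from 10 to 20 Mb and 44 of 113 on chromosome 7 from 100 to 110 Mb. The share over all these genes was 11.0%. Further windows, chosen after the values were seen, were chromosome 17 from 60 to 70 Mb with 25 of 78 and chromosome 20 from 50 to 60 Mb with 18 of 60. Windows on other chromosomes had shares as high. Some groups of nearby genes, chosen after their values were seen, had high deposited ratios in the authors' deposited table, such as APPBP2, PPM1D, BCAS3 and TBX2 on chromosome 17 (9.58, 9.51, 9.84 and 18.1 from 60443149 to 61409466, GRCh38) and HIPK1, BCAS2, DENND2C and NRAS on chromosome 1 (5.43, 6.14, 4.21 and 6.06 from 113929192 to 114716894), where BCAS stands for breast carcinoma amplified sequence. Around them the ratios were lower, with medians of 4.50 over the listed genes of chromosome 17 from 60 to 70 Mb and 3.31 over those of chromosome 1 from 110 to 120 Mb, against 3.28 for all listed genes. Chromosome 11, which carries TMEM25, had the lowest share at 4.5%, with chromosomes 9 and 3 close to it at 5.3% and 6.4%. The highest shares were 19.2% on chromosome X, 18.2% on chromosome 21 and 17.4% on chromosome 2. A link to the TMEM25 locus was not tested. Across chromosomes the share had an SD of 3.81 percentage points, above the 95% range of 1.34 to 2.69 when blocks of 20 neighbouring genes were moved. The spread across chromosomes decides nothing on the cause, because how many unlisted genes are silent is not known.

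A candidate explanation is that DNA copy number differed between the cells of the libraries, whether by clone or by origin, and others are short-range regulation or shared sequence of neighbouring genes. Pairs of genes under 1 Mb apart were both listed 1.69 times as often as under permutation (95% range 0.957 to 1.04), and pairs 5 to 10 Mb apart 1.12 times (0.944 to 1.06), and when blocks of 20 neighbouring genes were moved together the values were 1.26 (0.941 to 1.07) under 1 Mb, 1.29 (0.902 to 1.10) at 1 to 3 Mb and 1.13 (0.910 to 1.10) at 5 to 10 Mb. These values decide nothing, because listing needs a knockout value of at least 1, how many unlisted genes are silent is not known, and regions of silent genes raise such values at any distance. Ratios among the listed genes gave an uneven picture. Rank correlations were 0.0783 under 1 Mb (permuted range -0.0289 to 0.0312), 0.0189 at 1 to 3 Mb (-0.0301 to 0.0261) and 0.0526 at 5 to 10 Mb (-0.0226 to 0.0215). When blocks of 5 listed genes were moved together the ranges were 0.00257 to 0.0665, -0.0194 to 0.0489 and -0.0249 to 0.0298. Under both, the values under 1 Mb and at 5 to 10 Mb lay above their range and that at 1 to 3 Mb inside. Among 63 windows with at least 10 listed genes the highest median ratio, 8.4, was below the 8.87 typical of permuted genes. This comparison cannot exclude regional differences. Windows with few listed genes largely set the permuted maximum, and a median over 10 Mb can hide shorter runs of high ratios. These explanations cannot be told apart, no DNA was analysed here, and an effect of the knockout itself stays open as untested.

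The identity of the cells is an open point tied to this one, since parts of chromosomes 1 and 17 near these genes are known as amplified in luminal breast cancer lines such as MCF-7, which was not tested because no list of such genes was fixed beforehand. MDA-MB-231 is known as a mesenchymal-like line that lacks the estrogen receptor, yet the 4 mesenchymal list members had a median value of 0.67 in the wild-type library and 6.06 in the knockout library, against 106 and 239 for the 3 epithelial members. Those medians decide nothing, because a gene high in both libraries would not be listed. TFF1, a product of luminal cells, reached 5920 in the knockout library, while TIMP1, IL6 and CXCL8 were at 4.89, 0.03 and 0.40 in the wild-type library. Another cell line in one library or in both could give such values, but with 2 of 12 luminal markers and 4 of 24 mesenchymal genes listed it cannot be told apart from a change of cell state, which the design leaves as the biological alternative.

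The direction of the comparison rests on column headers. Counts, values and the ratio column pointed the same way in 2046 of 2046 genes, while both log2 headers ran the other way. A swap of genotypes could reverse the reading of every gene, and without a value for TMEM25 it cannot be told apart from a slip in the log2 headers alone.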
